A study of Mus musculus with 4 samples.

How the data were processed

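Total RNA sequencing of mouse kidney was analysed in 4 libraries, 2 from animals given no drug and 2 from animals given zafirlukast, all collected after bilateral kidney ischemia and reperfusion. Per the labels, RNA was taken with TRIzol or, as an alternative, a column kit; the labels do not tell which sample had which, and they place all samples in a single batch. Libraries were prepared by a standard Illumina procedure, per the labels' protocols. The submitters' processing notes name the genome build GRCm39. The aligner, the counting tool, the gene annotation release and the strand setting are not given in the sources used here.

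The deposited table gives a whole-number count and an FPKM value for each gene in each library, per the file headers. FPKM, a length- and depth-scaled fragment count, divides a gene's count by its length and by the library's depth. The deposited FPKM values were checked against the counts: the depth implied by the ratio of FPKM to count matched the total count multiplied by edgeR's TMM (trimmed mean of M values) factor over all genes, with implied factors of 1.03, 0.992, 0.973 and 1.01 for no drug replicates 1 and 2 and zafirlukast replicates 1 and 2. FPKM values are therefore already scaled between libraries and sum to different totals per library. The table held 56747 genes and 1 line that names no gene, which was left out. Gene symbols were taken from the table, which pairs 54054 of the gene identifiers with a symbol. Coordinates are those of the table. A reference annotation of the older build GRCm38 was used only to look up which identifiers occur in both and to compare 5 mitochondrial genes with their nuclear copies.

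Low even counts outnumbered low odd counts in all 4 libraries. In no drug replicate 1, for example, 3770 genes had an even count between 2 and 20 and 3261 had an odd count between 1 and 19. Counting both mates of a read pair gives such an excess and overstates the depth; whether it was done is not given in the sources used here. The counts were used as deposited, and an alternative divided them by 2. Reads were also counted for near-identical copies of a sequence: pseudogenes on chromosome 1 that copy mitochondrial genes carried almost the same counts as those genes, except that the copy of mt-Atp6 carried more than mt-Atp6. Values of genes with near-identical copies, overlapping genes or shared exons are uncertain for this reason, among them the mitochondrial genes, ribosomal protein genes, Ugt1a9 and Cyp4a14.

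Total counts were 34374143 and 27712955 for no drug replicates 1 and 2 and 29013371 and 28162163 for zafirlukast replicates 1 and 2. Intervals and floors that follow from counts cover counting error only. The labels do not say that the 2 libraries of a group came from separate animals, although the study describes groups of 6 mice; p-values measure the spread between these libraries. The 2 libraries of each group were compared for identity before use. A chi-square test of their counts gave 175 per gene in the no drug group and 46.1 per gene in the zafirlukast group, so neither pair agreed within sampling noise.

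Differences between groups were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, default filter for low counts, no covariate) on the counts of the 17440 genes that passed the filter, in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over those genes, with a threshold of 0.05. The design written before the data were examined named limma on FPKM as the test and edgeR in its place if counts were deposited; limma 3.58.1 on log2(FPKM + 1) became an alternative. FPKM is given as mean ± SD of 2 libraries. Fold values named in the text are ratios of group mean FPKM, and log2 fold changes are edgeR estimates with standard errors.

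A set of 47 gene lists was fixed before the data were examined. They cover the drug target, extracellular traps, macrophage activation, cell types of the kidney and of neighbouring tissues, injury, cell death, stress, metabolism and RNA quality. Lists were tested with camera in limma (preset correlation 0.01, two-sided) on log2(FPKM + 1) over the 13173 genes with a mean FPKM of at least 1. The 40 lists with at least 5 members among those genes were tested, with Benjamini-Hochberg adjustment over the 40. List values are medians over members of the difference in mean log2(FPKM + 1), zafirlukast minus no drug, a scale that understates the change of genes with low FPKM. Calls were repeated with the correlation estimated for each list and with fry. With an estimated correlation, camera rests on the residual degrees of freedom of 4 libraries and not on the number of genes. It then has little power, so a lost call does not show that correlation between members was the reason. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. Several lists share members.

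Genes named in the text follow a rule fixed before the data were examined. It takes the 10 genes with the largest rise and the 10 with the largest fall that pass the threshold without overlap of the groups. Where fewer pass, it fills up to 10 by the smallest unadjusted p among genes with at least a 2-fold difference and no overlap. It adds 3 members of each called list and 2 members of each other list on the drug target, the study question, injury or cell death. Cysltr1, Cysltr2, Alox5, Padi4, Padi2, Adgre1, Havcr1 and Lcn2 are always named. Clone and predicted-model names were passed over. The rule named 85 genes, and 2 of these are left out of the report.

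The edgeR step was tested on simulated counts drawn from the means and library sizes of these samples over 17440 genes, with 200 genes of moderate or high counts changed, for the comparison of zafirlukast with no drug. It recovered 1 of 50 genes changed 2-fold, 29 of 50 changed 4-fold, 48 of 50 changed 8-fold and 49 of 50 changed 16-fold. It called 14 of 17240 unchanged genes. The prior degrees of freedom were 10.0 in the simulated counts and 2.79 in the real counts, so these recovery rates do not carry over to the real test. In the real counts the gene Egf had a log2 fold change of 5.10 and did not pass (edgeR adjusted p = 0.102). A result of 0 calls therefore does not exclude large changes. In the simulated list test over 13173 genes, camera called 20 of 20 lists shifted by 1 on the log2 scale and 0 of 200 unshifted lists, where members were drawn without correlation.

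Alternatives covered the test (DESeq2 1.42.0, limma on FPKM), filters, scaling, pseudocounts, the dispersion prior, the replicate number as a block, and leaving out each library. Some were chosen after seeing the data: edgeR's newer dispersion moderation, limma-voom, counts divided by 2, camera on log2 depth-scaled counts, camera with a variance trend, and the lists without mt-Atp6. The design text also mentions tacrolimus; samples with that drug and unoperated kidneys were not analysed here.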

Results

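Gene expression was measured by RNA sequencing in mouse kidneys after bilateral ischemia of 30 min and reperfusion for 24 h, a model of acute kidney injury. One group received no drug and the other received zafirlukast, an antagonist of the cysteinyl leukotriene receptor CysLT1, at 10 mg/kg/day by mouth for 1 day beforehand. The series concerns extracellular traps released by macrophages in this injury, and the comparison asks how the kidney transcriptome differs with the drug. Each group had 2 libraries, with total counts between 27712955 and 34374143 and between 22102 and 22909 genes with a count. Unoperated kidneys were not analysed here, so all values are relative between these groups of injured kidneys.

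The zafirlukast libraries were close to each other and the no drug libraries were not. Across the 13173 genes with a mean FPKM of at least 1, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.975 between the zafirlukast libraries and 0.930 between the no drug libraries. No drug replicate 1 had r = 0.938 with zafirlukast replicate 2, above its value with no drug replicate 2. The lowest r, 0.831, was between no drug replicate 2 and zafirlukast replicate 1. The first principal component held 74.8% of the variance and separated the groups, with no drug replicate 1 between no drug replicate 2 and the zafirlukast libraries. The second, with 17.2%, set no drug replicate 1 apart.

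**Figure D1:**
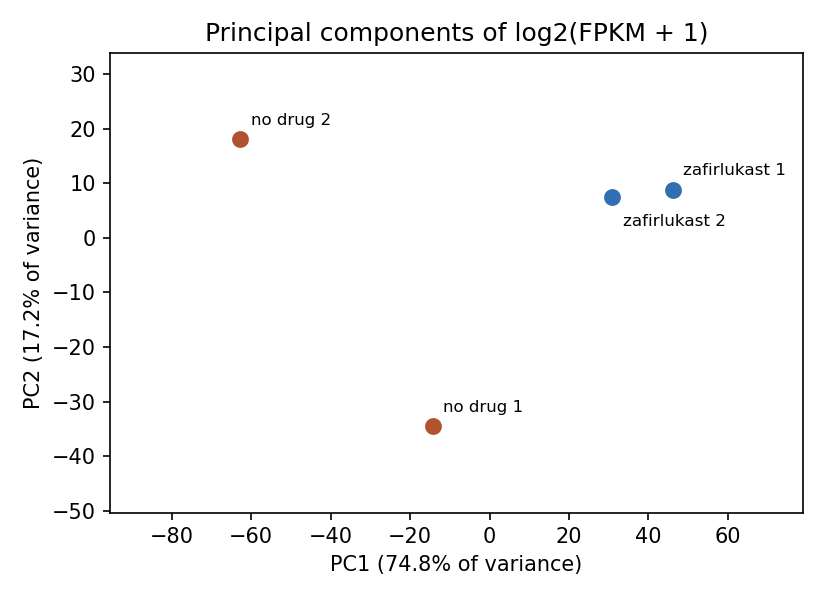
Principal components 1 (x axis) and 2 (y axis) of log2(FPKM + 1) over 13173 genes, with 1 point per library, colored by group. The zafirlukast libraries lie at 46.1 and 30.9 on component 1, and the no drug libraries at -14.3 and -62.7.

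No single gene passed the test between kidneys given zafirlukast and kidneys given no drug. At camera's preset correlation the list of injury markers was called lower and lists of tubule segments higher with zafirlukast. No list was called with an estimated correlation (smallest adjusted p = 0.442 with an estimated correlation). That form of camera has little power with 4 libraries. For proximal tubule segment S3, with an estimated correlation of -0.012, the unadjusted camera p went from 9.29e-06 to 0.043. The edgeR quasi-likelihood test called 0 genes higher and 0 genes lower among 17440, with a smallest adjusted p of 0.102. At an unadjusted p under 0.05 it gave 3501 genes, 1687 higher and 1814 lower, where 872 are expected by chance. DESeq2 called 799 higher and 782 lower, and limma on log2(FPKM + 1) called 0 higher and 1 lower. With the replicate number as a block, a pairing that the labels do not state, edgeR called 233 higher and 216 lower. Of the 1581 DESeq2 calls, 1541 had an unadjusted edgeR p under 0.05. Without no drug replicate 1, edgeR called 1863 higher and 1456 lower, in a fit that assumes the lone no drug library varies like the zafirlukast libraries; without any other library it called 0. The groups did not overlap at 10140 genes (58.1%), where 33.3% is the mean share over all splits of 4 distinct values into pairs. Genes do not vary independently, so the share of any 1 split can lie far from that mean. The difference from 33.3% is therefore no test of a group effect. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so none was run on single genes.

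The genes with the smallest unadjusted p that were higher with zafirlukast included Egf, which encodes epidermal growth factor and is made in the thick ascending limb and distal tubule. Egf (ENSMUSG00000028017, chromosome 3, 129471214 to 129548965, GRCm39) had 2.80 ± 1.13 FPKM without drug and 96.4 ± 24.9 with zafirlukast (SD, n = 2), a log2 fold change of 5.10 (SE 0.44, edgeR adjusted p = 0.102). Mep1b, the beta subunit of the brush border protease meprin, had 2.80 ± 0.49 and 44.8 ± 14.2 FPKM. Slco4c1, an organic anion transporter of the proximal tubule, had 0.378 ± 0.158 and 8.31 ± 0.15 FPKM, a 21.96-fold higher mean. Cyp7b1, an oxysterol hydroxylase, was 5.27-fold higher, and Pxmp2, a peroxisomal membrane channel, 5.82-fold higher. Uroc1, the urocanate hydratase of histidine breakdown, was 10.9-fold higher. Fam107a was 15.9-fold, Wfdc15b 10.3-fold, Abca13 14.8-fold and Nccrp1 45.9-fold higher. None of these 10 genes passed the test.

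Among the genes lower with zafirlukast, Tnc, which encodes the matrix protein tenascin C, had 14.9 ± 4.3 FPKM without drug and 1.28 ± 0.18 with zafirlukast (log2 fold change -3.55, SE 0.30, edgeR adjusted p = 0.102). Timp1, an inhibitor of matrix metalloproteinases, had 33.7 ± 0.6 and 4.85 ± 0.83 FPKM. Vgf, a neuropeptide precursor, had counts of 521 and 290 without drug against 8 and 8 with zafirlukast. Ugt1a9, a glucuronosyltransferase that shares exons with its neighbours and is uncertain for that reason, had counts of 850 and 440 against 14 and 18. Slc25a24, a mitochondrial ATP-Mg/phosphate carrier, had 25.9 ± 0.6 and 3.48 ± 0.30 FPKM. The no drug mean was 11.4 times the zafirlukast mean for Il1r2, the decoy receptor for interleukin 1, and 8.02 times for Angptl7. It was 6.61 times for Rcan3, 5.94 times for Emp1 and 3.92 times for Sema3c, a secreted semaphorin. None of the 10 passed the test.

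Tubular injury markers fell as a list by a median of 2.64 log2 units (camera adjusted p = 2.45e-11), a call that was lost when the correlation was estimated, at 0.61 (adjusted p = 0.52 with an estimated correlation). At 23 of the 24 members both zafirlukast libraries lay below both no drug libraries. Over all genes tested 0 members were called, and 16 were called lower adjusted over the list alone. Havcr1 (ENSMUSG00000040405, chromosome 11, 46625907 to 46670405), which encodes kidney injury molecule 1, had 1086 and 1434 FPKM without drug and 6.62 and 83.0 with zafirlukast (log2 fold change -4.82, SE 1.27, edgeR adjusted p = 0.172). Lcn2 (ENSMUSG00000026822, chromosome 2, 32274645 to 32278264), which encodes the injury marker NGAL, had 193 and 516 against 8.09 and 37.4 FPKM (log2 fold change -3.97, SE 0.94, edgeR adjusted p = 0.159). Hmox1, the heme-degrading oxygenase, had 466 ± 258 and 35.5 ± 2.6 FPKM, and Clu, the secreted chaperone clusterin, 558 ± 14 and 99.2 ± 36.6. The same markers also differed inside groups: their median was 0.96 log2 units lower in zafirlukast replicate 1 than in replicate 2 and 0.49 lower in no drug replicate 1 than in replicate 2.

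**Figure D2:**
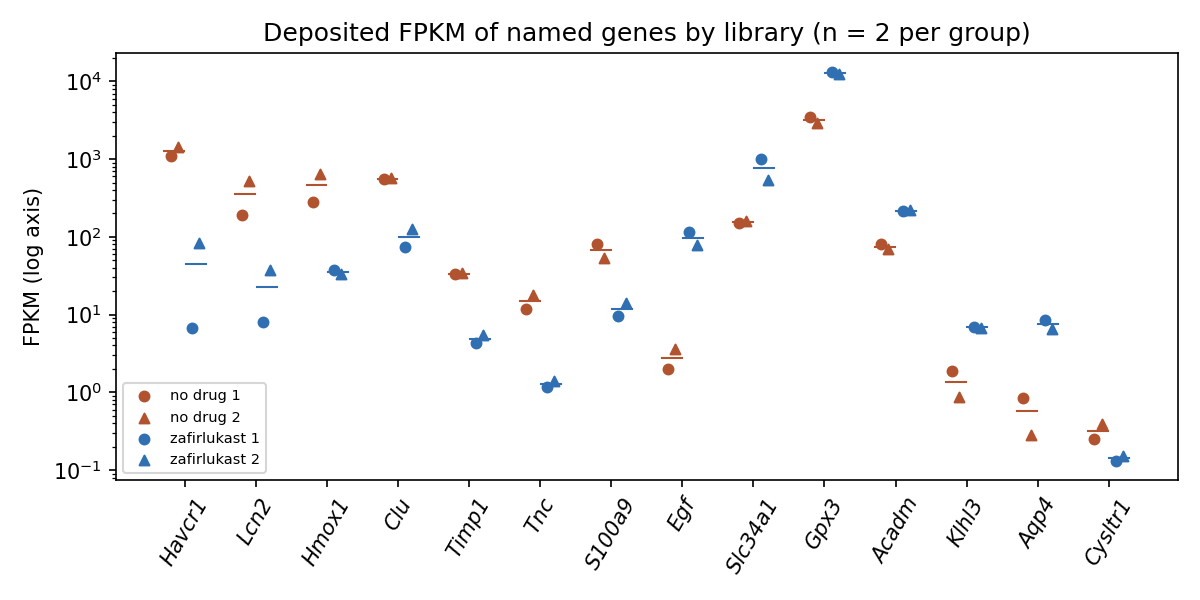
Deposited FPKM (y axis, log scale) of 14 named genes (x axis) in each of the 4 libraries, with circles for replicate 1, triangles for replicate 2 and lines for group means. Havcr1 lay at 1086 and 1434 without drug and at 6.62 and 83.0 with zafirlukast, and Egf at 1.996 and 3.60 against 114 and 78.8.

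All 6 fixed lists of tubule segments rose at the preset correlation, and none was called with an estimated correlation (adjusted p = 0.44 to 0.52 with an estimated correlation). The largest medians were those of the thick ascending limb, 1.87 over 10 members (camera adjusted p = 3.77e-08; adjusted p = 0.44 with an estimated correlation), and of proximal tubule segments S1 and S2, 1.85 over 20 members (adjusted p = 8.63e-10; adjusted p = 0.52 with an estimated correlation). Both zafirlukast libraries lay above both no drug libraries at all 30 of these members. Over all genes tested 0 were called; adjusted over the list alone, 8 of the 10 and 12 of the 20 were called higher. Slc34a1, the main phosphate transporter of the proximal tubule, had 156 ± 5 FPKM without drug and 773 ± 325 with zafirlukast. Its relative Slc34a3 had 1.77 ± 0.69 and 14.6 ± 5.1 FPKM, and Slc22a8, the organic anion transporter OAT3, 21.9 ± 0.9 and 87.1 ± 35.1. In the thick ascending limb list, Tmem72 had 2.15 ± 0.04 and 7.54 ± 0.26 FPKM, and Cldn19, a tight junction protein of magnesium transport, 2.70 ± 0.76 and 10.6 ± 0.2. The medians of S1 and S2 markers also differed within groups, by 1.12 between no drug replicates 1 and 2.

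The S3 segment list rose by a median of 1.35 (adjusted p = 4.65e-05; adjusted p = 0.44 with an estimated correlation) and collecting duct principal cells by 0.86 (adjusted p = 5.33e-05; adjusted p = 0.44 with an estimated correlation). Intercalated cells rose by 0.65 (adjusted p = 0.00071; adjusted p = 0.44 with an estimated correlation) and the distal convoluted and connecting tubule by 0.62 (adjusted p = 0.00385; adjusted p = 0.45 with an estimated correlation). Over all genes tested 0 members were called; adjusted over the list alone, 6 of 11, 5 of 11, 0 of 10 and 4 of 10 were called higher. Slc22a13, a urate and organic anion transporter, had 11.98 ± 0.34 and 43.98 ± 0.96 FPKM, and Slc5a8, a lactate transporter, 17.3 ± 1.1 and 48.6 ± 5.4. The water channels Aqp4 and Aqp3 had 0.569 ± 0.401 and 7.47 ± 1.38 FPKM and 23.7 ± 8.1 and 58.8 ± 12.7 FPKM, and the vasopressin receptor gene Avpr2 1.62 ± 0.69 and 5.62 ± 0.55. Of intercalated cells, the proton pump subunit Atp6v1b1 had 5.89 ± 5.15 and 24.1 ± 1.6 FPKM, Aqp6 5.97 ± 4.11 and 18.6 ± 2.9, and the transcription factor Hmx2 1.13 ± 0.14 and 2.38 ± 0.25. Klhl3, which controls the salt transporter of the distal convoluted tubule, had 1.37 ± 0.70 and 6.88 ± 0.11 FPKM, Klk1 989 ± 72 and 1578 ± 114, and Pvalb counts of 7 and 0 against 146 and 52. The distal convoluted list was not called without no drug replicate 1, where its median was 0.60.

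Markers of cells outside the tubule did not pass the test, except those of neutrophils. The podocyte median was 0.22 (adjusted p = 0.071), the endothelial median 0.09 (adjusted p = 0.251), and the median of fibroblasts, mural and juxtaglomerular cells 0.05 with a mean of -0.05 (camera adjusted p = 0.973); 0 of their members were called over all genes tested or adjusted over the list alone. Neutrophil markers fell by a median of 1.32 over 10 members (camera adjusted p = 1.10e-05; adjusted p = 0.44 with an estimated correlation). Of the 13 members tested by edgeR, 11 were lower in both zafirlukast libraries; 0 were called over all genes tested and 9 adjusted over the list alone. S100a9, a calcium-binding protein abundant in neutrophils, had 67.9 ± 19.3 and 11.9 ± 3.2 FPKM, and the lectin receptor gene Clec4d 2.93 ± 0.24 and 0.608 ± 0.205. The red blood cell median was 1.11 (adjusted p = 0.067) and rested on zafirlukast replicate 1, which lay 2.15 above replicate 2; the list was called higher without replicate 2, at a median of 2.16. Its members gave 0 calls on either adjustment.

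The 22 macrophage and monocyte markers moved both ways. Of these, 7 were higher in both zafirlukast libraries, 4 were lower in both and 11 overlapped. Over the 15 members above the FPKM minimum the median was 0.09 and the mean -0.38 (camera adjusted p = 0.973). The list had 0 members called over all genes and 1 called lower adjusted over the list alone. Adgre1, which encodes the macrophage marker F4/80, had 1.31 ± 0.91 FPKM without drug and 3.15 ± 0.06 with zafirlukast (log2 fold change 1.26, SE 0.55, edgeR adjusted p = 0.284). Chil3, a chitinase-like protein of alternatively activated macrophages and monocytes, had 11.6 ± 3.8 and 0.920 ± 0.227 FPKM. Mrc1, the mannose receptor gene, had 1.48 ± 1.11 and 0.660 ± 0.237 FPKM and overlapped between groups. The list of alternative activation held only 2 genes above the FPKM minimum and was not tested; 2 members were called lower and 1 higher adjusted over the list alone. The median of inflammatory activation genes was -1.02 over 6 members (adjusted p = 0.105), with counts of 189 and 409 against 13 and 28 for Ptgs2 and 55 and 242 against 8 and 8 for Il6. Adjusted over the list alone 1 member was called lower, and over all genes tested 0. That list was called lower without zafirlukast replicate 2, at a median of -1.36.

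The extracellular trap list and the leukotriene list, which bear on the series' question and on the drug's target, were not called by camera. The test of fry for change in either direction, which does not compare a list with other genes, called both (adjusted p = 0.0388 and 0.0188), and its directional test called neither (adjusted p = 0.249 and 0.296). The trap list had a median of -0.36 over 10 members (camera adjusted p = 0.18), with 3 members called lower and 1 higher adjusted over the list alone and 0 over all genes tested. Its members did not move together. S100a9 was lower with zafirlukast, as given above, while Cybb, the catalytic subunit of the phagocyte oxidase, had 0.852 ± 0.062 and 2.10 ± 0.09 FPKM. The trap list shares S100a8, S100a9, Mmp9, Camp and Ltf with the neutrophil list, so these lists are not independent. Padi4, the histone-citrullinating enzyme of trap formation, had counts of 21 and 6 without drug and 6 and 12 with zafirlukast. Padi2 had 82 and 23 against 51 and 29. Both overlapped between groups. The trap list was called lower without zafirlukast replicate 2, at a median of -0.54.

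The leukotriene list had a median of 0.17 over 9 members (adjusted p = 0.112), with 3 members called higher adjusted over the list alone and 0 over all genes tested. Cysltr1 (ENSMUSG00000052821, chromosome X, 105617952 to 105647285), the receptor that zafirlukast blocks, had counts of 46 and 55 without drug and 19 and 22 with zafirlukast (log2 fold change -1.19, SE 0.50, edgeR adjusted p = 0.273). Cysltr2 had counts of 25 and 0 against 33 and 9, and Alox5, the first enzyme of leukotriene synthesis, 39 and 12 against 25 and 11. The members with the smallest unadjusted p were Dpep1, a brush border dipeptidase that converts leukotriene D4 to E4, with 18.1 ± 2.2 and 39.2 ± 8.2 FPKM, and Oxgr1, a receptor for oxoglutarate and leukotriene E4, with 2.29 ± 1.25 and 8.93 ± 1.11. Both are also expressed in tubule cells.

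Several lists of stress, inflammation and cell death fell at the preset correlation and none with an estimated correlation. Immediate early genes had a median of -1.56 (adjusted p = 6.84e-07; adjusted p = 0.52 with an estimated correlation), with Atf3 at 9.46 ± 2.98 and 1.49 ± 0.58 FPKM, Myc at 14.03 ± 2.88 and 4.30 ± 1.28, and Fos at 4.96 ± 1.87 and 1.15 ± 0.35. The NF-kappaB list had a median of -1.21 (adjusted p = 0.00155; adjusted p = 0.61 with an estimated correlation), with Birc3 at 8.95 ± 2.79 and 2.79 ± 0.45 FPKM and Nfkb2 at 16.2 ± 1.1 and 6.58 ± 2.91. Adjusted over the list alone, 12 of 16 and 2 of 16 members of these lists were called lower, and 0 over all genes tested. The p53 target list fell by a median of 0.66 (adjusted p = 0.019; adjusted p = 0.58 with an estimated correlation), with 2 of 14 members called lower adjusted over the list alone and 0 over all genes tested. Gdf15, a stress-induced cytokine, had 80.2 ± 7.6 and 9.56 ± 7.78 FPKM, Btg2 38.0 ± 15.6 and 9.49 ± 3.61, and the apoptosis effector Bax 41.9 ± 3.9 and 25.001 ± 1.223.

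The necroptosis and apoptosis list fell by a median of 0.62 (adjusted p = 0.00904; adjusted p = 0.49 with an estimated correlation), with Mlkl, the pore-forming effector of necroptosis, at 4.62 ± 0.70 and 1.41 ± 0.26 FPKM. Casp8 was at 24.5 ± 3.0 and 11.9 ± 2.4, and Bak1 at 16.05 ± 2.34 and 8.21 ± 0.83. The ferroptosis list fell by a median of 0.90 (adjusted p = 0.00275; adjusted p = 0.52 with an estimated correlation), with Gch1, the first enzyme of tetrahydrobiopterin synthesis, at 4.12 ± 2.70 and 0.461 ± 0.115 FPKM. Its members Hmox1 and Ptgs2 also belong to other lists. Cell death itself was not measured, so a lower median of these lists does not show less of it. Adjusted over the list alone, 3 of 19 and 8 of 16 members were called lower and 0 and 1 higher, with 0 over all genes tested. The inflammasome list had 4 genes above the FPKM minimum and was not tested; Il1b had 3.83 ± 1.49 and 2.15 ± 1.96 FPKM and overlapped between groups, and Ninj1 47.0 ± 3.5 and 38.5 ± 1.3.

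The NRF2 and glutathione list fell by a median of 1.00 (adjusted p = 0.036; adjusted p = 0.52 with an estimated correlation), but its members went both ways. Adjusted over the list alone, 13 of 22 were called lower and 3 higher, with 0 over all genes tested. Srxn1, which repairs oxidized peroxiredoxins, had 250.0 ± 81.2 and 35.5 ± 6.5 FPKM. Gpx3, a glutathione peroxidase secreted by the proximal tubule, had 3193 ± 365 FPKM without drug and 12830.3 ± 342.0 with zafirlukast, and Gpx1 65.5 ± 4.7 and 215 ± 2 (edgeR adjusted p = 0.102 and 0.109). The extracellular matrix list fell by a median of 0.64 (adjusted p = 0.00217; adjusted p = 0.44 with an estimated correlation), with 7 of 20 members called lower adjusted over the list alone and 0 over all genes tested. The matrix list was not called without no drug replicate 1, where its median was -0.25.

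Nuclear genes of oxidative phosphorylation had a median of 0.48 over 24 members (adjusted p = 1.20e-05; adjusted p = 0.58 with an estimated correlation), of which 19 were higher in both zafirlukast libraries. Sdha, a subunit of succinate dehydrogenase, had 109 ± 18 and 190 ± 12 FPKM, Ndufs3 37.0 ± 4.0 and 58.4 ± 3.5, and Cox7a2 98.5 ± 18.0 and 167 ± 18. Fatty acid oxidation genes had a median of 0.32 (adjusted p = 0.00931; adjusted p = 0.61 with an estimated correlation). Acadm, the medium-chain acyl-CoA dehydrogenase, had 74.3 ± 7.8 and 218 ± 6 FPKM, the coactivator Ppargc1a 4.56 ± 0.93 and 13.1 ± 0.4, and Cyp4a14 102 ± 14 and 487 ± 156. Over all genes tested 0 members of either list were called, against 0 and 5 called higher adjusted over the list alone. The fatty acid list was not called without zafirlukast replicate 2, where its median was 0.17.

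The 13 protein genes of the mitochondrial genome had a median of 0.28 (camera adjusted p = 0.0496; adjusted p = 0.61 with an estimated correlation), with 0 members called over all genes or adjusted over the list alone. Apart from the estimated correlation and fry, the call was lost in 10 alternatives, among them the fits without no drug replicate 1, no drug replicate 2 or zafirlukast replicate 1, with medians of 0.31, 0.23 and 0.13. mt-Nd4 had 5991 ± 504 and 7893 ± 1224 FPKM and mt-Nd4l 3970 ± 246 and 5248 ± 660. mt-Atp6 had 8787 FPKM in no drug replicate 2 and between 1906 and 2359 in the other libraries. Copies of 5 of these genes on chromosome 1 carried similar or larger counts, so the values of mitochondrial genes are uncertain. Mitochondrial genes took 9.74% and 9.63% of counts without drug and 11.9% and 10.2% with zafirlukast.

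**Figure D3:**
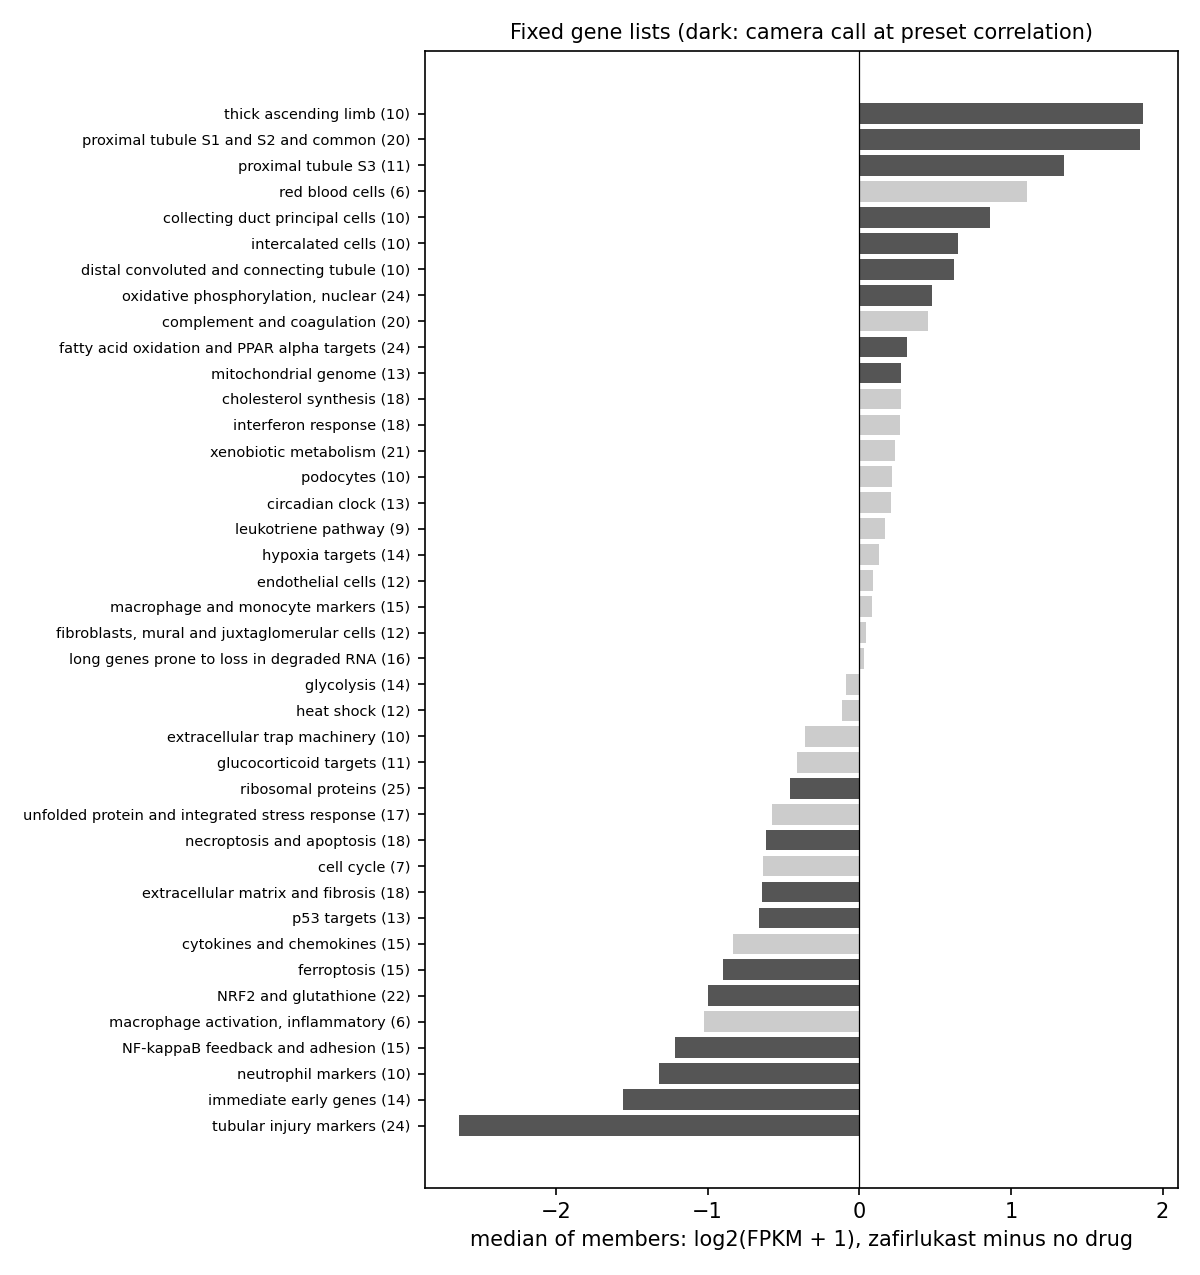
Median over members of the difference in log2(FPKM + 1), zafirlukast minus no drug (x axis), for the 40 lists tested (y axis, with the number of members), where dark bars mark lists called by camera at the preset correlation. Tubular injury markers lay at -2.64 and the thick ascending limb at 1.87; no list was called with an estimated correlation.

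Ribosomal protein genes, fixed as a sign of RNA quality, fell with zafirlukast by a median of 0.46 (camera adjusted p = 3.95e-07; adjusted p = 0.52 with an estimated correlation). Of the 25 members, 24 were lower in both zafirlukast libraries, and 0 were called over all genes or adjusted over the list alone; Rplp0 had 610 ± 50 and 385 ± 17 FPKM and Rplp1 1112 ± 101 and 704 ± 40. Long genes prone to loss in degraded RNA had a median of 0.03 (camera adjusted p = 0.521) and 0 members called on either adjustment.

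Across the 40 lists, camera called 9 higher and 10 lower at the preset correlation. With an estimated correlation it called 0, with a smallest adjusted p of 0.442; at the preset correlation 25 lists had an unadjusted p under 0.05. The directional test of fry called 0 and its test for change in either direction called 18, among them the trap, leukotriene, macrophage and monocyte, fibroblast, xenobiotic metabolism, hypoxia and complement lists, which camera did not call. Other lists that were not called had medians of -0.83 for cytokines and chemokines (camera adjusted p = 0.112), -0.63 for the cell cycle (0.105), -0.58 for the unfolded protein response (0.127), -0.41 for glucocorticoid targets (0.0743), -0.11 for heat shock (0.112) and -0.09 for glycolysis (0.928). Values above 0 were 0.45 for complement and coagulation (0.592, mean -0.71), 0.27 for cholesterol synthesis (0.161), 0.27 for the interferon response (0.0577), 0.24 for xenobiotic metabolism (0.0569), 0.21 for the circadian clock (0.0743) and 0.13 for hypoxia targets (0.463). Over all genes tested 0 members of these lists were called. Adjusted over the list alone, 3 members of complement were called lower and 1 higher, 2 each of glycolysis and glucocorticoid targets and 1 of the unfolded protein response lower, and 2 each of xenobiotic metabolism and the circadian clock and 1 of cholesterol synthesis higher, with 0 in the rest. Without zafirlukast replicate 2, calls were gained by cytokines (median -1.16), the unfolded protein response (-0.68), glucocorticoid targets (-0.48), heat shock (-0.18), the interferon response (0.49), xenobiotic metabolism (0.41), the circadian clock (0.37) and cholesterol synthesis (0.29). The cell cycle list was called without no drug replicate 2 (median -1.02) or zafirlukast replicate 1 (-0.82), without an FPKM minimum (-0.36), at a minimum of 0.1 (-0.38), on TPM (-0.76) and on log2 depth-scaled counts (-0.75), the circadian clock without no drug replicate 2 (0.25), glucocorticoid targets without no drug replicate 1 (-1.05) and at a minimum of 0.1 (-0.41), and xenobiotic metabolism without zafirlukast replicate 1 (0.0031) and after quantile normalization (0.28). Lists of adipocytes, the adrenal gland, skeletal muscle, B and plasma cells, and T and NK cells had 4, 1, 0, 2 and 0 genes above the FPKM minimum and were not tested. Of their members, 2 adipocyte genes were called lower adjusted over the list alone and 0 of the others. The no drug libraries differed at these neighbouring tissues. Relative to no drug replicate 2, no drug replicate 1 was lower by a median of 1.28 log2 units over the 4 adipocyte genes and by 3.24 at the 1 adrenal gene.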

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

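Chosen after the data were seen were edgeR with legacy=FALSE, limma-voom, counts divided by 2, camera on log2 depth-scaled counts or with a variance trend, and the lists without mt-Atp6; the other alternatives were planned. Of 30 alternatives for single genes, 14 gave a call in some direction, against 0 higher and 0 lower as reported. DESeq2 called 799 genes higher and 782 lower; it left the adjusted p of 8289 genes with counts as NA. Leaving out 1 library gave 0 to 1863 genes higher and 0 to 1456 lower, where the upper values came without no drug replicate 1 and each of the other 3 fits gave 0. Limma on log2(FPKM + 1) called 0 higher and 1 lower, a microRNA gene with no symbol (ENSMUSG00002076457, counts of 213 and 216 against 1 and 1) that was named after its values were seen. The count lower was also 1 with a pseudocount of 0.1 or 0.5, rescaling by median ratios, to TPM or without mitochondrial and top 20 genes, no trend, a robust prior, and edgeR with legacy=FALSE. Quantile normalization gave 5 higher and 2 lower. Limma-voom, counts divided by 2, other filters, other edgeR scalings, an edgeR fit with a robust prior or no abundance trend, a threshold of 0.1 and a 2-fold minimum gave 0 in both directions; at an unadjusted p under 0.05 limma-voom gave 3599 genes, limma on log2(FPKM + 1) 2962 and DESeq2 3793. The cause of these differences was not tested. The median log2 difference of all genes was between -0.050 and -0.00044 under the other scalings, and -0.0058 in the main edgeR fit.

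The labels do not say that a shared replicate number marks a shared animal or day. Same-numbered libraries deviated together with r = 0.21 across 13173 genes. With the replicate number as a block, edgeR called 233 genes higher and 216 lower, and limma on FPKM 467 and 382. The block gave 11 lists higher and 15 lower. Calls were gained by inflammatory macrophage activation (median -1.02, adjusted p = 0.0166), cytokines, the cell cycle, the unfolded protein response and glucocorticoid targets, all lower, and by red blood cells, the interferon response and xenobiotic metabolism, all higher; the mitochondrial genome lost its call.

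Camera called 8 to 13 lists higher except for 7 without no drug replicate 1, and 10 to 16 lists lower, over the preset-correlation alternatives. Leaving out 1 library gave 7 to 13 higher and 10 to 16 lower, the highest of both without zafirlukast replicate 2. With the correlation estimated, and with fry, 0 were higher and 0 lower. Of the 19 called lists, 15 kept their call in all 16 other camera alternatives; the exceptions were the distal convoluted tubule, extracellular matrix, fatty acid oxidation and mitochondrial genome lists. Podocytes were called without a filter and with a minimum of 0.1, with a median of 0.25. The cell cycle list was called without a filter (adjusted p = 0.00114), at a minimum of 0.1 (0.00282), on TPM (0.00475), on log2 depth-scaled counts (0.00133), with the block (0.0427) and without no drug replicate 2 (0.00338) or zafirlukast replicate 1 (0.0310). Glucocorticoid targets were also called at a minimum of 0.1 (adjusted p = 0.0482) and xenobiotic metabolism after quantile normalization (0.0446). A robust prior was not run for camera, which does not have one.

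The direction reversed only in lists and genes that were not called. For macrophage markers, whose median was 0.086 as reported, with the replicate block and with fry, it was 0.10 when rescaled without mitochondrial and top 20 genes and -0.039 to 0.51 with 1 library left out. For fibroblasts and mural cells the median was 0.045 with the block and with fry, 0.079 without a filter and at a minimum FPKM of 0.1, 0.13 on TPM, 0.26 on log2 depth-scaled counts and -0.069 to 0.16 with 1 library left out. For complement it was 0.45 with the block and with fry and 0.30 to 0.46 with 1 library left out, and for glycolysis -0.24 to 0.16. In some of these the direction of the test differed from the sign of the median. With 1 library left out, the log2 fold change was -2.05 to 0.17 for mt-Atp6, -0.15 to 7.38 for Cysltr2, -0.96 to 0.53 for Alox5, -0.89 to 0.52 for Padi4 and -0.71 to 0.74 for Padi2. Of the values of named genes under alternatives, 2079 kept their side of the threshold, 236 passed it and 8 reversed; 70 of the 85 named genes were called in at least 1 alternative.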

Other observations

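The pathway test, the genes near absent in a group and the tests of the 3 patterns were chosen after the data were seen, except those of a mixed library, of thinning and of the reference sequences. Among 229 KEGG pathways annotated in the deposited table, camera called 35 higher and 44 lower with zafirlukast at the preset correlation. With an estimated correlation, a form with little power at 4 libraries, it called 0 (smallest adjusted p = 0.637 with an estimated correlation). Of the pathways called higher, valine, leucine and isoleucine degradation had a median log2 difference of 0.75 over 45 genes (adjusted p = 7.15e-10), with 84.4% of members higher in both zafirlukast libraries. The median was 0.98 for tryptophan metabolism, 1.05 for glycine, serine and threonine metabolism, 0.89 for glyoxylate metabolism, 0.50 for the citrate cycle and 0.35 for the peroxisome. Lower pathways included ribosome biogenesis (-0.41 over 72 genes, adjusted p = 6.90e-07) and the proteasome (-0.43 over 54 genes, adjusted p = 2.17e-06), each with 77.8% of members lower in both zafirlukast libraries. The median was -0.53 for IL-17 signaling and -0.23 for the spliceosome.

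A small set of genes was near absent in 1 group, with at most 3 counts summed over both of its libraries and at least 20 in each library of the other. There were 15 such genes for no drug and 23 for zafirlukast, against 1 and 2, and 1 and 3, in the other pairings of the 4 libraries. Every pair of the other pairings mixes both groups, so a gene near absent in 1 group cannot qualify there. The numbers of the other pairings are therefore not those expected by chance. With a floor of 3 counts over the group, Car5a, a mitochondrial carbonic anhydrase, was at least 116-fold higher with zafirlukast (counts of 0 and 0 against 168 and 153). Serpina1e was at least 147-fold higher, although its near-identical paralogs make that value uncertain. In the other direction, Has1, a hyaluronan synthase, had counts of 70 and 43 against 0 and 0, at least 34.2-fold lower with zafirlukast, and the chemokine gene Ccl11 had 20 and 25 against 0 and 0. Gm3776, a glutathione transferase gene with close relatives, had 859 and 427 against 0 and 0. These genes were named after their values were seen, and none passed edgeR's adjusted threshold.

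The contrast of lower injury markers and higher tubule markers was set against 2 explanations. These were a smaller share of proximal tubule cells alone and a gene length trend from RNA breakdown. A smaller share of only those cells without drug would raise the markers of all other segments there. The lower quartile of the thick ascending limb members was instead 1.27 log2 units above 0 with zafirlukast. That list is part of the contrast, and its values were known before the test. Fewer tubule cells of several segments without drug could give the same values, and this was not tested. A trend with gene length would move genes of about the same length alike, but the proximal tubule member nearest in length lay above the injury member by a median of 4.35 log2 units (lower quartile 3.33) at the 20 of 24 injury members with such a partner within 10% of their length, which drew on 8 proximal tubule members. Ribosomal proteins, a list fixed as a sign of RNA quality, also fell with zafirlukast by a median of 0.46 (camera adjusted p = 3.95e-07; adjusted p = 0.52 with an estimated correlation), and a difference in RNA quality other than a length trend was not tested. Kidneys that differed in injury for reasons other than the drug stay open and cannot be told apart from an effect of zafirlukast, because each kidney had only 1 treatment; the injury median differed by -0.96 between zafirlukast replicates 1 and 2 while the proximal tubule median differed by 0.47, so the same axis also varied inside a group.

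No drug replicate 1 lay at 0.479 of the distance from no drug replicate 2 to the zafirlukast mean on principal component 1. Depth does not account for it: thinned to the smallest total, it lay at 0.478. A mixture with zafirlukast RNA fitted best at 51%, but 52.6% of 38 genes near absent in no drug replicate 2 were below 0.5 times the level that share needs, which argues against mixing as the whole of the shift. A zafirlukast kidney with the wrong label would lie near the zafirlukast mean at most injury markers, but 20 of 24 lay nearer to no drug replicate 2. Across 13173 genes, r of no drug replicate 1 was 0.938 with zafirlukast replicate 2, 0.918 with zafirlukast replicate 1 and 0.930 with no drug replicate 2. The injury median also differed by -0.96 between zafirlukast replicates 1 and 2. These values therefore do not settle whether the label was wrong. The injury median was 0.49 lower and the proximal tubule median 1.12 higher in no drug replicate 1 than in replicate 2, but whether that kidney had a milder injury was not tested, and the design names no other biological difference.

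mt-Atp6 had counts of 164492 in no drug replicate 2 against 45907, 45362 and 37031 in the other libraries. Its copy Gm10925 (chromosome 1, 24653055 to 24653732) had 174967 against 234481, 233505 and 191593, so the ratio of gene to copy was 0.94 in that library and 0.19 to 0.20 elsewhere. At the other 4 pairs of gene and copy the ratio was between 1.01 and 1.04 in every library. At mt-Atp6, no drug replicate 2 thus lay nearest to those pairs, and whether the departure lay in the other 3 libraries was not tested. A higher transcript level is argued against by mt-Atp8, from the same transcript, at 0.830 times the mean of the other libraries. Another handling of reads with several matches is argued against by the other 4 gene and copy pairs, whose ratios in that library differed from the others by a factor of at most 1.003. A mitochondrial sequence in no drug replicate 2 that differs from the other 3 libraries would need a base that tells gene and copy apart, but the GRCm38 reference sequences had 0 differences over 678 bases; the authors' build is GRCm39, and the source of the gap stays open.

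The 3 splits of the 4 libraries into pairs are too few for a share under 0.05. The real split gave 3501 genes at an unadjusted edgeR p under 0.05, a number that 1 of the 3 splits reached, the real one included, and the highest other split gave 179. Every pair of the other splits mixes both groups. The group difference adds to their spread, so 179 is not the number expected by chance.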
